A study of Mus musculus with 8 samples.

How the data were processed

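RNA of sorted mouse thymocytes was measured on 8 Illumina bead arrays on 1 slide, with 2 arrays for each combination of fraction (Foxp3+ or Foxp3-) and genotype (wild type or E-protein knockout). Per the labels, RNA was purified with a Qiagen column kit, amplified and biotin-labelled with the Illumina TotalPrep kit, and read with GenomeStudio 2011.1. Slide positions follow the groups, so that an effect of position and an effect of group cannot be told apart. Groups were taken from the sample labels, which give no sex, age or mouse number.

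The deposited table of unnormalized values holds the average bead signal of 25697 probes as intensity on a linear scale, without background subtraction. Beside each signal the authors give a detection p-value against the negative control beads of the array, in steps of 1 in 798. The deposited normalized table holds log2 values of 14942 probes. These are the probes with a detection p under 0.1 on at least 2 arrays, quantile normalized without background subtraction. Recomputing that normalization from the signals gave the same values to within 5e-09. No per-sample column of the tables was left unused.

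Probes were named with the gene table supplied for the deposited probes, which gave 1 symbol to 14017 probes, several to 0 and none to 925. Of these, 14010 matched a gene of the NCBI RefSeq table for the mouse assembly GRCm38.p6, used here only for names and for the order of genes along chromosomes. The labels name no genome build.

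The analysis started from the signals and detection p-values. With R 4.3.3 and limma 3.58.1, neqc corrected the background with the detection p-values, added an offset of 16, quantile normalized and took log2 values. Probes with a detection p under 0.05 on at least 2 of 8 arrays were kept (13526, of which 824 had no symbol), and each gene was represented by its probe with the highest mean, which left 9137 named genes and 824 unnamed probes. A linear model with 1 mean per group (4 residual degrees of freedom, prior degrees of freedom 3.74, typical SD 0.128) was fitted with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all 9961 tested, with calls at an adjusted p under 0.05. Errors are the SE of the moderated fit, or the SD where stated. The 5 comparisons were knockout against wild type in each fraction, Foxp3+ against Foxp3- in each genotype, and the difference between the knockout effects (Foxp3+ minus Foxp3-).

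The 25 gene lists were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the lists of a comparison. Camera asks whether the genes of a list move more than the other genes, and fry whether they move, on balance, in 1 direction. Of the 25 lists, those past camera were 3, 10, 12, 11 and 13 in the order of the comparisons above, and with an estimated correlation 1, 0, 2, 2 and 0. Each list's count was also taken with p-values adjusted over the list alone. The lists, the comparisons, the tests, the rule for naming genes and most alternatives were chosen before the data were examined.

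Genes were named by a fixed rule. It took every E protein and Id gene on the array. It took the 10 largest rises and 10 largest falls per comparison (5 each for the difference between effects) among genes with an adjusted p under 0.05 and no overlap of the groups, leaving out provisional symbols. It also took up to 4 genes per list with the largest change, and the text names a part of these. A gene outside the rule is said to have been named after its values were seen. Where the arrays of the dimmer group were all at background for the tested probe, the fold is given as at least the ratio to the lowest detected signal of those arrays. Taking the detection of the tested probe, and not of any probe of the gene, was settled after values were seen.

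The method was tested on simulated data, in which 50 genes each were changed by 0.5, 1, 2 or -1 log2 units in the Foxp3- comparison. It recovered 44%, 72%, 96% and 72% of these, with 5 false among 147 calls (3.40%), and made 0 calls when no gene was changed. Camera there gave p = 2.45e-36 for 25 genes shifted by 0.5 and 0.627 for an unshifted list, which does not test its preset correlation. Of the 2501 genes with several detected probes, 0, 21, 3, 17 and 1 had probes called in opposite directions in the 5 comparisons. Of the 147, 962, 1181, 982 and 230 such genes called by any probe, 33, 218, 436, 264 and 50 were called by all of their probes.

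The alternatives tried were no background correction, median scaling, cyclic loess, the deposited log2 values, no detection filter, a stricter filter (detection p under 0.01 on at least 4 arrays), a trended robust variance, array weights, the replicate number as a block, only the 4 arrays compared, every detected probe, and leaving out each array in turn. For the direction of the knockout effect these were chosen after seeing the data. All 8 arrays were used. Probes failing the filter and the 2 genes Tcf3 and Id4, which were not named among the tested probes, were not analysed here. Raw image files were not used here.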

Results

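Messenger RNA was measured on 8 Illumina bead arrays, each holding RNA of thymocytes sorted from mice. Thymocytes were sorted as CD4+Foxp3+ cells, which include developing regulatory T cells (Treg cells), or as CD4 single-positive Foxp3- cells. The mice were wild type or lacked the E proteins E2A (gene Tcf3) and HEB (gene Tcf12), transcription factors that bind E-box DNA and steer T-cell development. All carried a Foxp3 knock-in allele. The floxed E-protein genes were deleted by a tamoxifen-activated Cre, with 4 oral doses of 3 mg tamoxifen per mouse over 10 days, which wild-type mice also received. Each of the 4 combinations of fraction and genotype had 2 arrays. The array number limits the precision of every value, and the labels do not say that the 2 replicates of a group came from separate mice, so that each p-value measures only the spread between arrays.

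Between 11462 and 12540 of the 25697 probes per array were detected above negative control beads (44.6% to 48.8%), and the median signal was 114 to 123 intensity units. After the detection filter, 9961 genes or unnamed probes were tested. Across these genes, arrays of the same group correlated at r = 0.989 to 0.996. Correlations were 0.974 to 0.985 for the same fraction of the other genotype and 0.945 to 0.967 for the other fraction of the same genotype. A principal component analysis placed 61.5% of the variance on the axis that separated the fractions, and 21% and 7.39% on the next axes. The replicate difference had an SD of 0.331 log2 units in knockout Foxp3+ arrays, against 0.197 to 0.228 in the other groups. Differences are given as log2 values from limma with their SE, n = 2 arrays per group. Each gene named as changed between 2 groups had an adjusted p under 0.05, and both arrays of 1 group lay above both arrays of the other.

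The transcripts of the E proteins and of their Id inhibitors were examined before the wider comparisons. Tcf12 fell by 1.06 ± 0.12 in knockout Foxp3+ thymocytes (adjusted p = 0.00322) and by 0.81 ± 0.12 in knockout Foxp3- thymocytes (adjusted p = 0.00369). Where its probe lies relative to the deleted part of the gene is unknown here. Tcf3 and Id4 were not named among the tested probes, so that loss of the E2A transcript was not measured. Id3, an E-protein inhibitor that E proteins themselves activate, fell by 1.83 ± 0.19 in Foxp3+ (adjusted p = 0.00196) and by 1.16 ± 0.19 in Foxp3- thymocytes (adjusted p = 0.00534). The knockout effects on Tcf12 and Id3 did not differ by a passing test between the fractions (differences -0.24, adjusted p = 0.461, and -0.66, adjusted p = 0.204). For Id3 that difference passed without wild-type Foxp3+ replicate 1 (adjusted p = 0.0433).

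Id2, another inhibitor of E proteins, was lower in Foxp3+ than in Foxp3- thymocytes, by -1.62 ± 0.17 in wild type (adjusted p = 0.000284) and -1.93 ± 0.17 in knockout (adjusted p = 0.000213). Its knockout effect was 0.24 in Foxp3+ (adjusted p = 0.462) and 0.55 in Foxp3- thymocytes (adjusted p = 0.0565), where it passed without either knockout Foxp3+ array (adjusted p = 0.00915). Settings such as cyclic loess (adjusted p = 0.0484) or array weights (adjusted p = 0.0161) also brought it past the threshold. The difference between its knockout effects was -0.31 (adjusted p = 0.505). In knockout thymocytes, Tcf12 was lower in the Foxp3+ fraction by -0.47 ± 0.12 (adjusted p = 0.0255). That call ended without knockout Foxp3+ replicate 2 (adjusted p = 0.0921), knockout Foxp3- replicate 1 (adjusted p = 0.133) or replicate 2 (adjusted p = 0.0639), and with cyclic loess (adjusted p = 0.0612) or only the 4 arrays compared (adjusted p = 0.0714). Id3 was lower there by -0.86 ± 0.19 (adjusted p = 0.0145), a call that ended without knockout Foxp3+ replicate 1 (adjusted p = 0.0503) or knockout Foxp3- replicate 1 (adjusted p = 0.0878). In wild type the fraction differences were -0.23 for Tcf12 (adjusted p = 0.184) and -0.20 for Id3 (adjusted p = 0.465), the latter passing without wild-type Foxp3+ replicate 2 (adjusted p = 0.0429).

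Id1 and Tcf4 (E2-2, another E protein) passed in no comparison. Id1 differed by 0.29 and -0.22 between genotypes in Foxp3+ and Foxp3- thymocytes, and by -0.11 and 0.40 between fractions in wild type and knockout. The last value passed without knockout Foxp3+ replicate 1 (adjusted p = 0.0138) or with cyclic loess (adjusted p = 0.0484), and the difference of 0.51 between the genotype effects passed without the same array (adjusted p = 0.0405). Tcf4 differed by 0.20 and -0.42 between genotypes and by 0.17 and 0.79 between fractions. Without knockout Foxp3+ replicate 2, its fraction difference in knockout (adjusted p = 0.0033) and its difference of 0.62 between the genotype effects (adjusted p = 0.0344) passed. The former also passed without background correction (adjusted p = 0.0376).

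**Figure D1:**
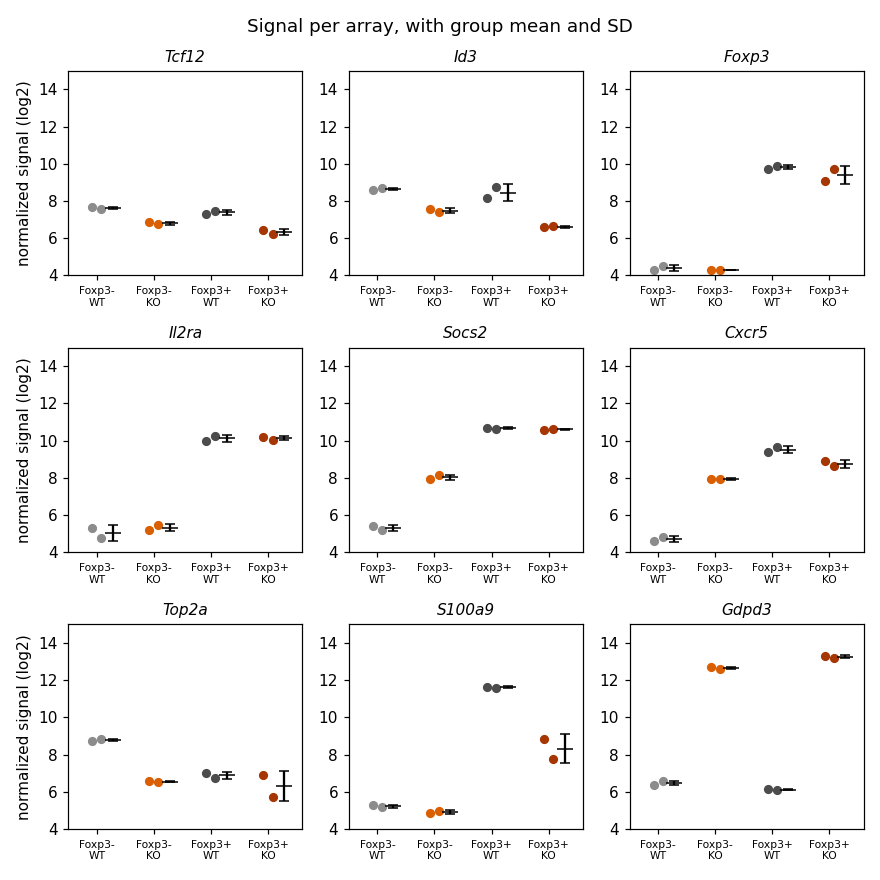
Normalized signal (log2) of 9 genes on each array (points) with the group mean and SD (bars), n = 2 arrays per group, in Foxp3- and Foxp3+ thymocytes of wild type (WT) and E-protein knockout (KO). Tcf12 and Id3 are lower in both knockout groups, Gdpd3 is at 6.48 and 6.11 in wild type and at 12.66 and 13.26 in knockout, and Socs2 and Cxcr5 in knockout Foxp3- arrays lie between the wild-type Foxp3- and Foxp3+ levels.

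Knockout and wild-type Foxp3+ thymocytes were compared to ask which transcripts depend on E proteins in cells that already express Foxp3. The largest rise was that of Gdpd3, which encodes a phospholipid-cleaving phosphodiesterase, by 7.15 ± 0.10 (142-fold, adjusted p = 4.68e-08). Cpne4, a calcium-dependent membrane-binding protein, rose by 3.12 ± 0.12 (at least 7.53-fold, adjusted p = 2.51e-05). The cytosolic DNA sensor Aim2 rose by 2.57 ± 0.12 (5.94-fold, adjusted p = 3.97e-05), Ctse, which encodes the protease cathepsin E, by 1.63 ± 0.15 (adjusted p = 0.000983), and Tnfaip3, an inhibitor of NF-kB signalling, by 1.66 ± 0.21 (adjusted p = 0.00461). The largest falls were in genes known from neutrophils and other myeloid cells. Il1b, an inflammatory cytokine, changed by -4.27 ± 0.17 (19.3-fold lower, adjusted p = 2.51e-05) and Retnlg, a resistin-like protein of neutrophils, by -4.24 ± 0.30 (19-fold lower, adjusted p = 0.000273). Foxp3 itself, the transcription factor that defines Treg cells, differed by -0.43 ± 0.21 (adjusted p = 0.284). Without knockout Foxp3+ replicate 2 the Foxp3 difference was -0.77 (adjusted p = 0.0257).

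Of 16 tested markers of myeloid and dendritic cells, 0 rose and 10 fell in knockout Foxp3+ thymocytes (0 and 13 adjusted over the list alone), with a median of -1.42 (camera adjusted p = 3.62e-15; adjusted p = 0.0449 with an estimated correlation). Among them were the antimicrobial calcium-binding proteins S100a8 (-3.23 ± 0.23, adjusted p = 0.00024) and S100a9 (-3.31 ± 0.29, adjusted p = 0.000864), the Fc receptor chain Fcer1g (-4.02 ± 0.20, adjusted p = 4.22e-05) and the neutrophil granule protein Ngp (-2.38 ± 0.10, adjusted p = 2.63e-05). Lcn2, an iron-sequestering granule protein, changed by -3.28 ± 0.21 (adjusted p = 0.000124), Chil3, a chitinase-like protein, by -3.05 ± 0.18 (adjusted p = 0.000103), and Hdc, which makes histamine, by -3.36 ± 0.11 (adjusted p = 9.42e-06). The fry test of the myeloid list gave an adjusted p = 0.000538. The lists of other non-T cells had smaller median differences, which were not tested against that of the myeloid list. Of 6 erythroid markers, 1 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 0.0508), the member that rose being the globin Hbb-b2 (2.63 ± 0.31, at least 5.73-fold, adjusted p = 0.00326). The erythroid list passed under 10 other settings (adjusted p from 0.00156 to 0.0403) but not with the stricter filter (adjusted p = 0.0676). It passed without wild-type Foxp3+ replicate 2 (adjusted p = 0.0362), either wild-type Foxp3- array (adjusted p = 0.0426) or knockout Foxp3+ replicate 1 (median 1.01, adjusted p = 2.79e-05), whereas without knockout Foxp3+ replicate 2 its median was 0.22 (adjusted p = 0.63). Of 12 B-cell markers 0 rose and 1 fell (0 and 1 adjusted over the list alone; median -0.21, camera adjusted p = 0.26). That list passed without knockout Foxp3+ replicate 1 (median -0.525, adjusted p = 1.84e-05) and with every detected probe (median -0.464, adjusted p = 0.0247), whereas its median was 0.133 without knockout Foxp3+ replicate 2.

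Cell cycle genes had a median of -0.37 in knockout Foxp3+ thymocytes, with 0 of 19 risen and 1 fallen (0 and 5 adjusted over the list alone; camera adjusted p = 0.00031; adjusted p = 0.702 with an estimated correlation). The list did not pass without knockout Foxp3+ replicate 2 (median -0.234, adjusted p = 0.106). The member that fell, named after its values were seen, was Tyms, a nucleotide-synthesis enzyme, with -0.54 ± 0.12 (adjusted p = 0.0429). Its call ended without any 1 of the 8 arrays. The adjusted p was 0.116 and 0.192 without wild-type Foxp3+ replicates 1 and 2, and 0.0607 and 0.0825 without knockout Foxp3+ replicates 1 and 2. It was 0.0654 without either wild-type Foxp3- array and 0.0797 without either knockout Foxp3- array. The call also ended with median scaling (adjusted p = 0.0667), array weights (0.101), the replicate block (0.062), only the 4 arrays compared (0.140) and every detected probe (0.0521). Genes of dissociation stress and heat shock had a median of 0.30, with 3 of 15 risen and 1 fallen (5 and 1 adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.359 with an estimated correlation), and a median of 0.166 without knockout Foxp3+ replicate 1. Fosb, an immediate-early transcription factor, rose by 0.91 ± 0.11 (adjusted p = 0.00326), while the stress-induced survival gene Ier3 changed by -1.31 ± 0.14 (adjusted p = 0.00187).

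No other list passed in this comparison. The Treg signature had 0 of 25 genes risen and 2 fallen (2 and 2 adjusted over the list alone; median -0.06, camera adjusted p = 0.46). Its member Klrg1, an inhibitory receptor, changed by -0.99 ± 0.16 (adjusted p = 0.0148, and 0.0839 with only the 4 arrays compared). Of 14 E-protein target genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.29, and 0.00364 with every probe tested). The chemokine receptor Cxcr4 rose by 0.99 ± 0.11 (adjusted p = 0.00231), and the cytokine-signal inhibitor Socs3 changed by -1.003 ± 0.13 (adjusted p = 0.00586, and 0.0509 with only the 4 arrays compared). Nfkbib, an NF-kB inhibitor, rose by 1.05 ± 0.12 (adjusted p = 0.00268) among 17 NF-kB genes, of which 2 rose and 1 fell (3 and 2 adjusted over the list alone). Of 11 NK and cytotoxic markers, 0 rose and 2 fell (0 and 3 adjusted over the list alone), with a median of -0.06, a mean of -0.71 and a camera adjusted p = 0.0755. Fcer1g (-4.02), also a myeloid marker, fell most. Tyrobp (-1.54), Plac8 (-1.28), Klrd1 (-1.01) and Ccl5 (-0.45) were also negative, and the others were at -0.06 to 0.30. The NK list passed under 7 other settings (adjusted p from 0.0191 to 0.0419). Its median was -0.105 and -0.45 without wild-type Foxp3+ replicates 1 and 2. It was -0.642 without knockout Foxp3+ replicate 1 and changed sign, to 0.262, without replicate 2. Markers of double-positive thymocytes, with 0 of 8 changed by either adjustment, including that adjusted over the list alone, had a median of 0.42 (camera adjusted p = 0.3) and passed without knockout Foxp3+ replicate 2 (median 0.922, adjusted p = 0.000672). Their median was 0.272 without wild-type Foxp3+ replicate 2 and changed sign, to -0.181, without knockout Foxp3+ replicate 1. Interferon-stimulated genes had 0 of 17 risen and 1 fallen, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.136). They passed with no filter (adjusted p = 0.00813) or every probe (0.018). Median and mean differed in sign for the 5 E protein and Id genes (0.20 and -0.43, test downward) and for 20 genes of the T-cell receptor (TCR) response (0.08 and -0.02, test downward).

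In all, 213 genes rose and 284 fell in knockout Foxp3+ thymocytes, 34 and 107 of them by over 2-fold. The total of 497 became 160 and 214 without wild-type Foxp3+ replicates 1 and 2, 298 without either wild-type Foxp3- array and 817 without knockout Foxp3+ replicate 2. It was 908 without background correction, 911 from the deposited log2 values, 892 with a trended robust variance, 304 with array weights and 140 with only the 4 arrays compared. Of the called genes, 42.9% were higher, and 26.3% under median scaling.

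In Foxp3- thymocytes the same comparison asked what differed with E-protein loss in the CD4 single-positive Foxp3- fraction. Gdpd3 again rose most, by 6.18 ± 0.10 (72.3-fold, adjusted p = 1.45e-07). The chemokine Ccl5 rose by 4.65 ± 0.38 (25-fold, adjusted p = 0.000223), the chemokine receptors Ccr6 and Cxcr5 by 3.66 ± 0.31 (12.7-fold, adjusted p = 0.000285) and 3.22 ± 0.15 (9.30-fold, adjusted p = 2.31e-05), and the inflammatory protease Casp1 by 3.59 ± 0.14 (12.0-fold, adjusted p = 1.05e-05). The largest fall was that of Tmem108, a transmembrane protein, with -4.16 ± 0.15 (at least 15.5-fold, adjusted p = 8.1e-06). Pclaf, a partner of the replication clamp PCNA, changed by -3.53 ± 0.14 (at least 8.46-fold lower, adjusted p = 1.05e-05). Foxp3 was detected on 0 of 2 wild-type and 0 of 2 knockout arrays of this fraction, and differed by -0.11 ± 0.21 between them (adjusted p = 0.758).

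Genes of the Treg signature were higher in knockout Foxp3- thymocytes, with 11 of 25 risen and 5 fallen (12 and 6 adjusted over the list alone; median 0.29, and 0.467 without wild-type Foxp3- replicate 1, camera adjusted p = 0.01; adjusted p = 0.166 with an estimated correlation). The cytokine-signal inhibitor Socs2 rose by 2.74 ± 0.12 (adjusted p = 2.07e-05), the integrin chain Itgae by 2.56 ± 0.23 (adjusted p = 0.000396), the G-protein regulator Rgs1 by 2.52 ± 0.13 (adjusted p = 4.01e-05) and the coreceptor Nrp1 by 1.93 ± 0.13 (adjusted p = 0.000102). T helper and follicular effector genes were higher too, with 10 of 13 risen and 0 fallen (10 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 7.87e-05; adjusted p = 0.166 with an estimated correlation). Ifng, the T helper type 1 cytokine, rose by 2.95 ± 0.12 (adjusted p = 1.53e-05), Cxcr3, a receptor of effector cells, by 2.63 ± 0.19 (adjusted p = 0.000163), and the lineage factor Tbx21 by 1.51 ± 0.23 (adjusted p = 0.00424). Of 13 chemokine receptor and trafficking genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.89, camera adjusted p = 0.000483; adjusted p = 0.139 with an estimated correlation). Cytokine receptor and JAK-STAT genes had 17 of 25 risen and 1 fallen (17 and 2 adjusted over the list alone; median 0.61, camera adjusted p = 2.59e-07; adjusted p = 0.139 with an estimated correlation). Among them were the receptor chain Il10ra (2.12 ± 0.12, adjusted p = 7.34e-05) and the feedback inhibitor Cish (1.68 ± 0.10, adjusted p = 8.2e-05). Of 17 NF-kB genes, 8 rose and 0 fell, also when adjusted over the list alone (median 0.31, camera adjusted p = 0.00299; adjusted p = 0.26 with an estimated correlation). Tnfaip3 rose by 1.49 ± 0.21 (adjusted p = 0.00265), Nfkbib by 1.46 ± 0.12 (adjusted p = 0.000223) and Traf1, a signalling adaptor, by 0.95 ± 0.10 (adjusted p = 0.000599).

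Mature single-positive thymocyte genes were higher as well, with 10 of 20 risen and 0 fallen (11 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.000228; adjusted p = 0.166 with an estimated correlation). Among them were Dapl1 (2.37 ± 0.16, adjusted p = 0.000109) and the surface protein Ly6c1 (1.82 ± 0.16, adjusted p = 0.000384). Cell cycle genes were lower, with 0 of 19 risen and 16 fallen (0 and 18 adjusted over the list alone; median -1.14, camera adjusted p = 1.56e-11; adjusted p = 0.139 with an estimated correlation). Top2a, the topoisomerase of dividing cells, changed by -2.25 ± 0.32 (4.76-fold lower, adjusted p = 0.00277), the mitotic kinase Cdk1 by -1.75 ± 0.29 (adjusted p = 0.00567) and Tyms, named after its values were seen, by -1.39 ± 0.12 (adjusted p = 0.000254). TCR response genes had 1 of 20 risen and 7 fallen, also when adjusted over the list alone (median -0.32, camera adjusted p = 0.00565; adjusted p = 0.139 with an estimated correlation). Itm2a, a gene of recently selected thymocytes, changed by -1.49 ± 0.24 (adjusted p = 0.00508), the costimulatory receptor Tnfrsf9 by -1.21 ± 0.14 (adjusted p = 0.00103) and the TCR-induced factor Egr2 by -0.84 ± 0.11 (adjusted p = 0.00194). Of 15 dissociation stress and heat shock genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.47, camera adjusted p = 2.24e-05; adjusted p = 0.139 with an estimated correlation). Fosb rose by 3.23 ± 0.11 (9.41-fold, adjusted p = 6.18e-06), Fos by 1.87 ± 0.23 (adjusted p = 0.00133) and Ier3 by 1.67 ± 0.14 (adjusted p = 0.000223). These stress genes rose in the same arrays as the Treg-signature and effector genes.

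Of the erythroid markers, 4 of 6 rose and 0 fell in knockout Foxp3- thymocytes (5 and 0 adjusted over the list alone; median 0.97, camera adjusted p = 0.00565; adjusted p = 0.427 with an estimated correlation). The globin Hba-a1 differed by 3.43 ± 0.19 (10.8-fold, adjusted p = 5.7e-05). Of 11 NK and cytotoxic markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.163), including the granule protein Nkg7 (2.41 ± 0.40, adjusted p = 0.00589). The NK list passed under 5 other settings (adjusted p from 0.0149 to 0.0427). Of 12 B-cell markers, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.28, camera adjusted p = 0.0949). The B-cell list passed under 5 other settings (adjusted p from 0.00797 to 0.0492), without either knockout Foxp3+ array (adjusted p = 0.00728) and without knockout Foxp3- replicate 1 (adjusted p = 0.0388). Myeloid markers had 4 of 16 risen and 0 fallen (4 and 1 adjusted over the list alone; median 0.03, camera adjusted p = 0.574), with the lysozyme Lyz2 up by 1.37 ± 0.18 (adjusted p = 0.00224) and S100a8 and S100a9 at -0.30 and -0.31. Double-positive thymocyte markers had 0 of 8 risen and 1 fallen (median -0.22, camera adjusted p = 0.256) and gamma-delta T-cell markers 0 of 4 risen and 2 fallen (median -0.24, camera adjusted p = 0.24), also when adjusted over the list alone. The only tested gene of epithelium and stroma differed by -0.0051 and was not called, also when adjusted over the list alone (adjusted p = 0.961).

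The remaining lists did not pass in Foxp3- thymocytes. The E proteins and Id genes had 0 of 5 risen and 2 fallen (1 and 2 adjusted over the list alone; median -0.42, camera adjusted p = 0.129, and 0.0423 with no filter). Of 14 E-protein targets, 4 rose and 0 fell, also when adjusted over the list alone (median 0.26, camera adjusted p = 0.142, and 0.0403 with no filter), among them Socs3 (1.58 ± 0.13, adjusted p = 0.000256), Cxcr4 (1.48 ± 0.11, adjusted p = 0.000145) and the survival receptor Il7r (0.83 ± 0.11, adjusted p = 0.00234). Conventional CD4 T genes lower in Treg cells had 2 of 8 risen and 1 fallen, also when adjusted over the list alone (median -0.01, mean 0.41, test upward, adjusted p = 0.683). TNF receptor and costimulation genes had 5 of 20 risen and 5 fallen (6 and 6 adjusted over the list alone; median -0.15, mean 0.11, test downward, adjusted p = 0.847). The TGF-beta pathway had 1 of 10 risen and 0 fallen, also when adjusted over the list alone (median -0.01, mean 0.03, test upward, adjusted p = 0.979). Lineage transcription factors had 5 of 15 risen and 2 fallen (5 and 3 adjusted over the list alone; median -0.05, mean 0.13, test downward, adjusted p = 0.961). Apoptosis regulators had 3 of 13 risen and 3 fallen, also when adjusted over the list alone (median 0.08, adjusted p = 0.743). The death ligand Fasl rose by 2.08 ± 0.15 (adjusted p = 0.00013). Interferon-stimulated genes had 3 of 17 risen and 3 fallen, also when adjusted over the list alone (median 0.01, mean -0.01, test downward, adjusted p = 0.934). Housekeeping genes had 0 of 9 risen and 1 fallen (0 and 0 adjusted over the list alone; median -0.14, adjusted p = 0.142, and 0.0403 with no filter).

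In all, 1192 genes rose and 943 fell in knockout Foxp3- thymocytes, 278 and 173 of them by over 2-fold. The total of 2135 was 829 and 975 without wild-type Foxp3- replicates 1 and 2, and 982 and 1049 without knockout Foxp3- replicates 1 and 2. Of the called genes, 55.8% were higher, and 44.7% under median scaling.

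Genes that moved the same way with E-protein loss in both fractions were counted next. In both, 123 genes rose and 87 fell, against 25.5 and 26.9 if the calls were independent, and 27 genes moved in opposite directions. Gdpd3 and Nfkbib were among those higher in both fractions, with values given above, and Tcf12 and Id3 among those lower. Tmem108, Cpne4, Pclaf and Il10ra were shared as well and lie on the chromosome of Tcf12, a point taken up below. Across the 9961 genes, which are not independent replicates, the knockout effects of the fractions correlated at r = 0.348 (rho = 0.345). The 210 shared genes became 64 and 101 without wild-type Foxp3+ replicates 1 and 2, 99 and 95 without wild-type Foxp3- replicates 1 and 2, 369 without knockout Foxp3+ replicate 2, and 113 and 107 without knockout Foxp3- replicates 1 and 2. They were 424 without background correction, 423 from the deposited log2 values, 389 with a trended robust variance, 133 with array weights and 64 with only the 4 arrays of each comparison.

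**Figure D2:**
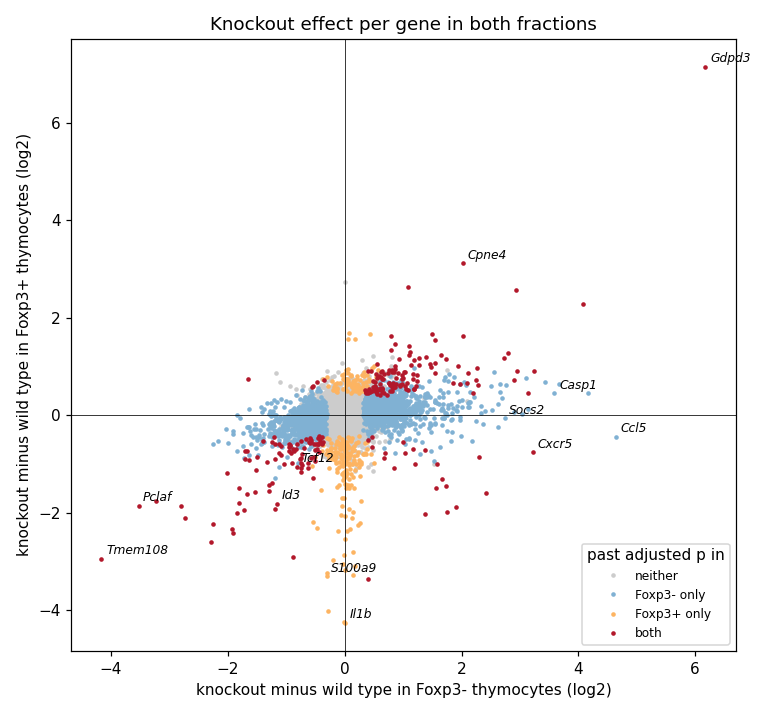
Knockout minus wild-type difference (log2) of each tested gene (points) in Foxp3- thymocytes on the horizontal axis and in Foxp3+ thymocytes on the vertical axis, coloured by the fraction in which the adjusted p passed. Gdpd3 lies near 6.18 and 7.15, Ccl5 and Cxcr5 lie to the right near the horizontal axis, and Il1b and S100a9 lie far down near the vertical axis.

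Foxp3+ and Foxp3- thymocytes of wild-type mice were compared to describe the Treg-lineage transcripts that set the fractions apart where E proteins were present. The Treg signature was higher in Foxp3+ cells, with 24 of 25 genes risen and 0 fallen, also when adjusted over the list alone (median 2.63, camera adjusted p = 2.4e-21; adjusted p = 0.0171 with an estimated correlation). Foxp3 was higher by 5.42 ± 0.21 (at least 33.9-fold, adjusted p = 1.93e-06), Socs2 by 5.37 ± 0.12 (41.4-fold, adjusted p = 3.51e-07), the interleukin 2 receptor chain Il2ra by 5.10 ± 0.20 (adjusted p = 2.04e-06) and the activation marker Cd83 by 5.04 ± 0.11 (adjusted p = 3.51e-07). Conventional CD4 T genes were lower, with 1 of 8 risen and 6 fallen (1 and 7 adjusted over the list alone; median -0.97, camera adjusted p = 0.00132; adjusted p = 0.109 with an estimated correlation). The coreceptor Tgfbr3 differed by -2.73 ± 0.11 (adjusted p = 2.76e-06), Igfbp4, a growth-factor binding protein, by -2.54 ± 0.11 (adjusted p = 3.12e-06) and Lef1, a transcription factor of immature and naive T cells, by -1.73 ± 0.16 (adjusted p = 0.000124). The largest falls included the adhesion receptor Adgrg3 (-3.65 ± 0.12, at least 10.5-fold, adjusted p = 1.18e-06), Itm2a (-3.41 ± 0.24, 10.7-fold, adjusted p = 3.3e-05), the cytokine Il4 (-3.06 ± 0.16, 8.33-fold, adjusted p = 6.97e-06), the receptor chain Il17rb (-2.93 ± 0.54, adjusted p = 0.0049) and the NK receptor Klra1 (-2.79 ± 0.13, adjusted p = 4.12e-06).

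Several signalling lists were higher in wild-type Foxp3+ thymocytes. Of 17 NF-kB genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.52, camera adjusted p = 6.02e-05; adjusted p = 0.194 with an estimated correlation). Traf1 differed by 1.82 ± 0.10 (adjusted p = 8.23e-06). Of 20 TNF receptor and costimulation genes, 10 rose and 4 fell (11 and 5 adjusted over the list alone; median 0.57, camera adjusted p = 0.00769; adjusted p = 0.313 with an estimated correlation). The checkpoint receptor Ctla4 differed by 3.74 ± 0.14 (adjusted p = 1.72e-06) and the costimulatory receptor Tnfrsf4 by 1.75 ± 0.16 (adjusted p = 0.000108). Cytokine receptor and JAK-STAT genes had 15 of 25 risen and 1 fallen (16 and 1 adjusted over the list alone; median 0.66, camera adjusted p = 9.22e-08; adjusted p = 0.0777 with an estimated correlation). Chemokine receptor and trafficking genes had 7 of 13 risen and 4 fallen, also when adjusted over the list alone (median 0.47, camera adjusted p = 0.0321; adjusted p = 0.298 with an estimated correlation). Ccr6 differed by 5.21 ± 0.31 (37.1-fold, adjusted p = 1.47e-05) and Cxcr5 by 4.80 ± 0.15 (adjusted p = 1.02e-06). The chemokine call ended with cyclic loess (adjusted p = 0.0583) and without wild-type Foxp3- replicate 1 (adjusted p = 0.0557). T helper and follicular effector genes had 7 of 13 risen and 2 fallen (8 and 3 adjusted over the list alone; median 0.48, camera adjusted p = 0.0362; adjusted p = 0.364 with an estimated correlation). Stress and heat shock genes had 10 of 15 risen and 0 fallen, also when adjusted over the list alone (median 0.76, camera adjusted p = 3.4e-05; adjusted p = 0.0717 with an estimated correlation). Fosb differed by 2.53 ± 0.11 (adjusted p = 2.86e-06). Cell cycle genes were lower, with 1 of 19 risen and 10 fallen (1 and 11 adjusted over the list alone; median -0.52, camera adjusted p = 0.00254; adjusted p = 0.344 with an estimated correlation), Top2a differing by -1.91 ± 0.32 (adjusted p = 0.00287). Mature single-positive thymocyte genes had 10 of 20 risen and 4 fallen (11 and 5 adjusted over the list alone; median 0.32, camera adjusted p = 0.0596). They passed under 5 other settings (adjusted p from 0.0101 to 0.0361) and without wild-type Foxp3+ replicate 1 (adjusted p = 0.0435) or wild-type Foxp3- replicate 2 (adjusted p = 0.0411).

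Markers of other cells were also higher in wild-type Foxp3+ than in Foxp3- thymocytes. RNA of such cells was not separated from that of T cells, so that the differences given above, Ccr6 and Cxcr5 included, need not all lie in T cells. All 16 myeloid markers rose, also when adjusted over the list alone (median 3.54, camera adjusted p = 7.62e-16; adjusted p = 0.0214 with an estimated correlation). S100a9 was higher by 6.41 ± 0.29 (84.8-fold), S100a8 by 6.37 ± 0.23 (82.5-fold), Lyz2 by 5.97 ± 0.18 (62.9-fold) and the complement chain C1qb by 4.18 ± 0.18. Of 12 B-cell markers, 8 rose and 0 fell (10 and 0 adjusted over the list alone; median 2.27, camera adjusted p = 2.09e-06; adjusted p = 0.313 with an estimated correlation). The antigen receptor chain Cd79b differed by 3.47 ± 0.34 (adjusted p = 0.000177). Of 6 erythroid markers, 4 rose and 0 fell, also when adjusted over the list alone (median 2.82, camera adjusted p = 0.000822; adjusted p = 0.344 with an estimated correlation). Hba-a1 differed by 4.56 ± 0.19 (adjusted p = 2.81e-06). Lyz1, a lysozyme, rose by 6.56 ± 0.15 (94.4-fold), the largest rise among the genes named for this comparison. The iron exporter Slc40a1 (5.85 ± 0.19, at least 43.6-fold) and the adhesion molecule Vcam1 (5.27 ± 0.19, at least 31.7-fold) were also higher. NK and cytotoxic markers had 4 of 11 risen and 6 fallen, also when adjusted over the list alone. Their median was -0.77 and their mean 0.18, with a downward test (adjusted p = 0.795). The other lists gave a camera adjusted p from 0.121 to 0.741. Apoptosis regulators (adjusted p = 0.0178) and gamma-delta T-cell markers (adjusted p = 0.0419) passed with no filter.

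In all, 1668 genes were higher and 1686 lower in wild-type Foxp3+ thymocytes, 661 and 300 of them by over 2-fold. The total of 3354 was 2233 without wild-type Foxp3+ replicate 1, and 2091 and 2003 without wild-type Foxp3- replicates 1 and 2. Of the called genes, 49.7% were higher, against 38.3% under median scaling and 60.6% with cyclic loess. Median scaling moved the median of all genes from -0.05 to -0.15 in this comparison and from -0.03 to -0.13 in knockout.

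In knockout mice the comparison of fractions asked whether the Foxp3+ profile persisted without E proteins. The Treg signature was higher in Foxp3+ cells, with 23 of 25 genes risen and 0 fallen, also when adjusted over the list alone (median 2.07, camera adjusted p = 2.58e-22; adjusted p = 0.0157 with an estimated correlation). Foxp3 was higher by 5.10 ± 0.21 (at least 24.3-fold, adjusted p = 1.05e-05), Il2ra by 4.80 ± 0.20 (27.9-fold, adjusted p = 1.05e-05), the Treg-associated factor Ikzf2 by 3.92 ± 0.23 (at least 13.5-fold, adjusted p = 2.88e-05), Cd83 by 3.81 ± 0.11 (14.0-fold, adjusted p = 2.55e-06) and Ctla4 by 3.67 ± 0.14 (12.7-fold, adjusted p = 9e-06). Conventional CD4 T genes had 0 of 8 risen and 7 fallen, also when adjusted over the list alone (median -0.90, camera adjusted p = 2.65e-06; adjusted p = 0.053 with an estimated correlation). Dapl1 differed by -3.04 ± 0.16 (8.21-fold lower, adjusted p = 2.08e-05), Igfbp4 by -2.42 ± 0.11 (adjusted p = 1.24e-05) and Tgfbr3 by -2.25 ± 0.11 (adjusted p = 1.71e-05). NK and cytotoxic markers were lower in knockout Foxp3+ cells, with 2 of 11 risen and 8 fallen, also when adjusted over the list alone. Their median was -2.02 (camera adjusted p = 0.00411, and 0.307 with an estimated correlation). The NK receptor Klrd1 differed by -4.44 ± 0.62 (21.8-fold, adjusted p = 0.00176), the chemokine Xcl1 by -3.18 ± 0.36 (9.03-fold, adjusted p = 0.000726), Ccl5 by -2.31 ± 0.38 (adjusted p = 0.00365) and Nkg7 by -2.21 ± 0.40 (adjusted p = 0.00658). Il4 was lower by -3.70 ± 0.16 (13.0-fold, adjusted p = 1.05e-05), Tbx21 by -1.99 ± 0.23 (adjusted p = 0.000828) and the chemokine receptor Cxcr6 by -3.04 ± 0.34 (8.21-fold, adjusted p = 0.000658), while Ccr6 was higher by 2.18 ± 0.31 (adjusted p = 0.00211).

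NF-kB genes had 5 of 17 risen and 1 fallen in knockout Foxp3+ cells (6 and 1 adjusted over the list alone; median 0.29, and 0.188 without knockout Foxp3+ replicate 2, camera adjusted p = 0.00922; adjusted p = 0.307 with an estimated correlation, and 0.0536 with median scaling). TNF receptor and costimulation genes had 8 of 20 risen and 2 fallen (8 and 4 adjusted over the list alone; median 0.20, camera adjusted p = 0.0341; adjusted p = 0.373 with an estimated correlation). That call ended without knockout Foxp3+ replicate 2 (median 0.0967), without knockout Foxp3- replicate 2 and with only the 4 arrays compared (adjusted p = 0.0508). The median was 0.308 without knockout Foxp3+ replicate 1. Cytokine receptor and JAK-STAT genes had 10 of 25 risen and 4 fallen (13 and 5 adjusted over the list alone; median 0.27, camera adjusted p = 0.00675; adjusted p = 0.307 with an estimated correlation). Interferon-stimulated genes had 2 of 17 risen and 7 fallen, also when adjusted over the list alone (median -0.27, and -0.405 without knockout Foxp3+ replicate 1, camera adjusted p = 0.0111; adjusted p = 0.307 with an estimated correlation, and 0.0779 with every probe), with the interferon regulator Irf7 at -1.48 ± 0.17 (adjusted p = 0.000658). Stress genes had 5 of 15 risen and 1 fallen, also when adjusted over the list alone (median 0.44, camera adjusted p = 0.0111; adjusted p = 0.234 with an estimated correlation). Cell cycle genes had 4 of 19 risen and 1 fallen, also when adjusted over the list alone (median 0.12, camera adjusted p = 0.289). The replication helicase subunit Mcm7 rose by 0.94 ± 0.19 (adjusted p = 0.00928). The cell cycle list passed without knockout Foxp3+ replicate 2 (median 0.276, adjusted p = 0.0108) and had a median of -0.137 without replicate 1. Double-positive thymocyte markers (median 0.251) passed without knockout Foxp3+ replicate 2 (median 0.971, adjusted p = 0.0406) and had a median of -0.478 without replicate 1, and housekeeping genes passed with every probe (adjusted p = 0.0286).

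Myeloid markers had 13 of 16 risen and 0 fallen (14 and 0 adjusted over the list alone; median 1.62, camera adjusted p = 4.33e-11; adjusted p = 0.0427 with an estimated correlation). S100a8 differed by 3.44 ± 0.23 (adjusted p = 5.58e-05) and S100a9 by 3.40 ± 0.29 (adjusted p = 0.000184). B-cell markers had 9 of 12 risen and 0 fallen (11 and 0 adjusted over the list alone; median 1.90, and 1.18 without knockout Foxp3+ replicate 1, camera adjusted p = 2.29e-06; adjusted p = 0.307 with an estimated correlation). Cd79b differed by 2.86 ± 0.34 (adjusted p = 0.000843). Erythroid markers had 5 of 6 risen and 0 fallen (6 and 0 adjusted over the list alone; median 1.78, camera adjusted p = 5e-05; adjusted p = 0.307 with an estimated correlation). The anion exchanger Slc4a1 differed by 3.01 ± 0.23 (adjusted p = 0.000118). Slc40a1 was higher by 5.11 ± 0.19 (at least 31.8-fold) and Gbp2b, an interferon-induced GTPase, by 5.03 ± 0.12 (at least 23.8-fold). Median and mean differed in sign for 5 of the lists that did not pass, the TCR response (-0.02 and 0.21, test upward), the TGF-beta pathway (0.08 and -0.12, test upward), mature single-positive genes (0.02 and -0.19, test downward), apoptosis regulators (0.13 and -0.02, test upward) and gamma-delta markers (-0.16 and 0.17, test downward).

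In all, 1291 genes were higher and 1298 lower in knockout Foxp3+ than in knockout Foxp3- thymocytes, 405 and 219 of them by over 2-fold. The total of 2589 was 1348 and 1643 without knockout Foxp3- replicates 1 and 2, and 1591 with only the 4 arrays compared. Of the called genes, 49.9% were higher, and 37.4% under median scaling. The fraction difference was shared between genotypes by 1662 genes, 896 higher and 766 lower in both, against 216 and 220 if the calls were independent, with 55 opposite. Across genes the fraction differences of the genotypes correlated at r = 0.737.

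**Figure D3:**
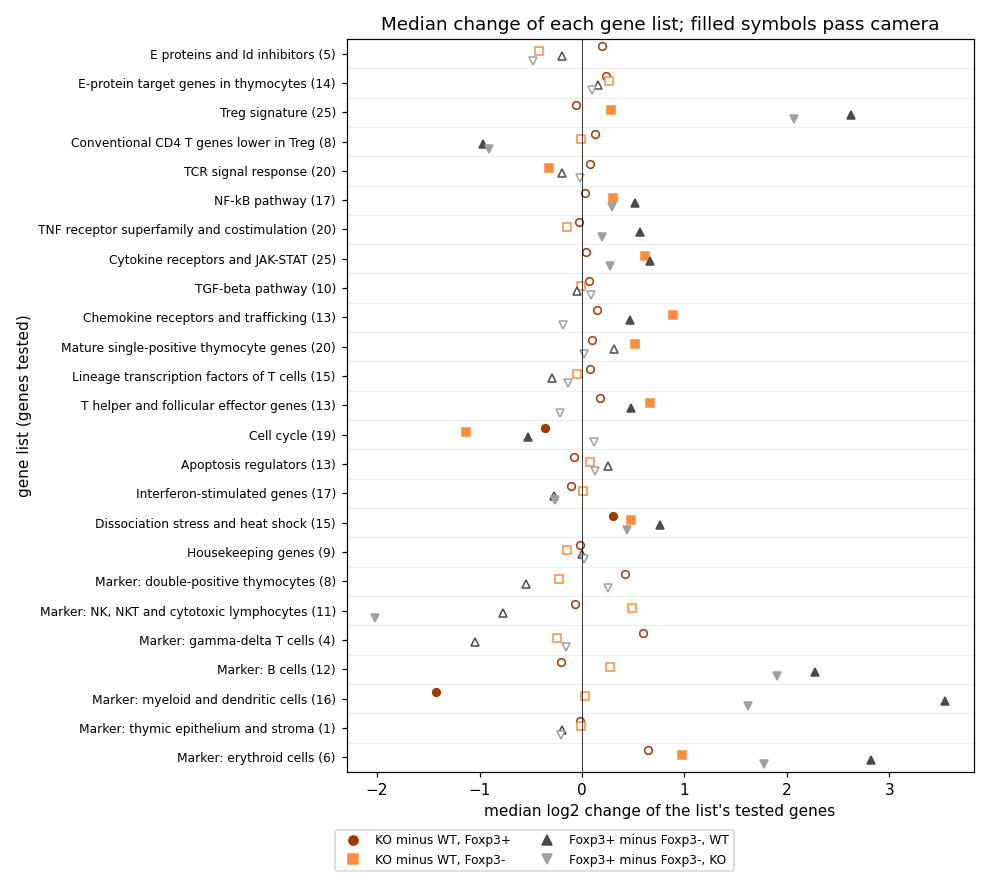
Median log2 difference (horizontal axis) of the tested genes of each list (vertical axis, with the number tested) in 4 comparisons, with filled symbols where camera with the preset correlation passed. The Treg signature and myeloid lists lie at 2.63 and 3.54 for wild type and at 2.07 and 1.62 for knockout in the comparisons of fractions, the cell cycle list lies lowest for knockout Foxp3- cells at -1.14, and the myeloid list lies at -1.42 for knockout Foxp3+ cells.

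The knockout effect in Foxp3- thymocytes was then set against the wild-type difference between Foxp3+ and Foxp3- cells, to ask whether E-protein loss moved Foxp3- cells along the Treg direction. Socs2 lay between the wild-type fractions, with 5.29 ± 0.18 (SD) in wild-type Foxp3-, 8.03 ± 0.14 in knockout Foxp3- and 10.67 ± 0.04 in wild-type Foxp3+ arrays. Cxcr5 was at 4.72, 7.94 and 9.52 in the same groups, whereas Il2ra was at 5.03, 5.32 and 10.14. Of 1213 genes called in both comparisons, 1056 (87.1%) moved in the same direction, 603 higher and 453 lower, against 200 and 160 if the calls were independent, and 157 moved in opposite directions. Across genes, which are not independent replicates, the differences correlated at r = 0.442 (rho = 0.432). Both differences subtract the same wild-type Foxp3- arrays. Data simulated without any effect therefore also correlated, at r = 0.50 on average and at most 0.532 over 100 simulations. Over all genes, 65.1% moved in the same direction, against 66.6% in the simulated data. The simulated values come from noise alone, whereas the observed differences also hold effects, so that neither of these comparisons can decide the question. The counts expected of independent calls leave out the shared arrays, and these or other cells may give part of the excess. The covariance of the differences was 0.155, against 0.0120 on average and at most 0.0133 in the simulated data. Noise of the simulated size in the shared arrays thus gave a small part of the covariance.

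The difference between the knockout effects of the fractions was tested gene by gene to ask where E-protein loss acted differently in Foxp3+ and Foxp3- cells. Positive values mean a knockout effect more positive in Foxp3+ cells. Ccl5 had the most negative difference, -5.10 (adjusted p = 0.00205), followed by Il1b (-4.28, adjusted p = 0.000172), Retnlg (-4.24, adjusted p = 0.00178), the protease inhibitor Slpi (-4.03, adjusted p = 2.5e-05) and Cxcr5 (-3.98, adjusted p = 0.000146). The most positive were Xist, the RNA that silences an X chromosome (2.39, adjusted p = 0.00154), the steroid-metabolising enzyme Akr1c18 (1.84, adjusted p = 0.000375), the peptide transporter Slc15a1 (1.75, adjusted p = 0.00154), the cohesin acetyltransferase Esco2 (1.73, adjusted p = 0.00672) and Pclaf (1.66, adjusted p = 0.00301). The labels give no sex, so that the Xist difference need not come from E-protein loss, and Y-linked genes are given beside it in the last paragraph. Both arrays of at least 1 group were at background for Il1b, Retnlg, Akr1c18, Slc15a1, Esco2 and Pclaf, so that the size of these differences depends on the background correction and is not exact. The difference of Foxp3 was -0.32 (adjusted p = 0.58) and that of Top2a was 1.67 (adjusted p = 0.0761). Top2a passed without knockout Foxp3+ replicate 1 (adjusted p = 0.0159) or 2 (adjusted p = 0.00115) and under 5 other settings (adjusted p from 0.00329 to 0.0493). Together 164 genes had a more positive and 414 a more negative knockout effect in Foxp3+ cells. The total of 578 was 308 and 266 without wild-type Foxp3+ replicates 1 and 2, 224 and 254 without wild-type Foxp3- replicates 1 and 2, and 258 and 293 without knockout Foxp3- replicates 1 and 2. It was 918 without background correction, 914 from the deposited log2 values and 911 with a trended robust variance.

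Several lists that were higher in knockout Foxp3- thymocytes had more negative differences. The Treg signature had 1 of 25 genes more positive and 11 more negative (3 and 11 adjusted over the list alone; median -0.32, and -0.491 without wild-type Foxp3- replicate 1, camera adjusted p = 0.000304; adjusted p = 0.12 with an estimated correlation). Socs2 differed by -2.80 (adjusted p = 0.000224), Rgs1 by -2.41 (adjusted p = 0.000517), Nrp1 by -1.85 (adjusted p = 0.00161) and the ectoenzyme Nt5e by -1.80 (adjusted p = 0.00117). T helper effector genes had 0 of 13 more positive and 5 more negative (0 and 7 adjusted over the list alone; median -0.64, camera adjusted p = 9.06e-05; adjusted p = 0.155 with an estimated correlation). Ccr6 differed by -3.03 (adjusted p = 0.00835) and Ifng by -2.05 (adjusted p = 0.000823). Chemokine receptor genes had 0 of 13 more positive and 5 more negative (0 and 9 adjusted over the list alone; median -0.66, camera adjusted p = 4.07e-05; adjusted p = 0.113 with an estimated correlation). Cytokine receptor and JAK-STAT genes had 0 of 25 more positive and 11 more negative (0 and 14 adjusted over the list alone; median -0.55, camera adjusted p = 1.58e-08; adjusted p = 0.113 with an estimated correlation). Mature single-positive genes had 0 of 20 more positive and 7 more negative (0 and 8 adjusted over the list alone; median -0.23, and -0.352 without knockout Foxp3+ replicate 2, camera adjusted p = 0.000466; adjusted p = 0.18 with an estimated correlation). NF-kB genes had 0 of 17 more positive and 2 more negative (0 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.0123; adjusted p = 0.315 with an estimated correlation), a call that ended without knockout Foxp3+ replicate 1 (adjusted p = 0.201). Stress genes had 0 of 15 more positive and 2 more negative (0 and 5 adjusted over the list alone; median -0.10, camera adjusted p = 0.0159; adjusted p = 0.155 with an estimated correlation, and 0.0503 with every probe), with medians of -0.0676 without wild-type Foxp3+ replicate 1 and -0.218 without knockout Foxp3+ replicate 2.

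Cell cycle genes had the opposite sign, with 2 of 19 more positive and 0 more negative (11 and 0 adjusted over the list alone; median 0.71, camera adjusted p = 4.35e-07; adjusted p = 0.155 with an estimated correlation), and so did TCR response genes, with 1 of 20 more positive and 0 more negative (2 and 0 adjusted over the list alone; median 0.35, and 0.226 without knockout Foxp3+ replicate 2, camera adjusted p = 0.00801; adjusted p = 0.155 with an estimated correlation). Among the marker lists, myeloid genes had 0 of 16 more positive and 8 more negative (0 and 15 adjusted over the list alone; median -1.26, camera adjusted p = 2.31e-13; adjusted p = 0.0571 with an estimated correlation). NK and cytotoxic genes had 0 of 11 more positive and 2 more negative, Ccl5 and the myeloid marker Fcer1g (0 and 6 adjusted over the list alone). The list median was -1.14 (camera adjusted p = 0.000263, and 0.189 with an estimated correlation). B-cell markers had 0 of 12 more positive and 4 more negative, also when adjusted over the list alone (median -0.59, camera adjusted p = 0.0133; adjusted p = 0.572 with an estimated correlation), a call that ended without knockout Foxp3+ replicate 2 (median -0.187, adjusted p = 0.105), while the median was -0.919 without replicate 1. Double-positive thymocyte markers had 0 of 8 changed (1 and 0 adjusted over the list alone; median 0.95, camera adjusted p = 0.0453; adjusted p = 0.605 with an estimated correlation). That call ended without wild-type Foxp3+ replicate 2 (adjusted p = 0.219), wild-type Foxp3- replicate 1 (adjusted p = 0.0663), knockout Foxp3+ replicate 1 (median 0.249, adjusted p = 0.441) or knockout Foxp3- replicate 1 (adjusted p = 0.0755), and the median was 1.58 without knockout Foxp3+ replicate 2. Gamma-delta markers had 0 of 4 changed, also when adjusted over the list alone (median 0.70, camera adjusted p = 0.0516), and passed under 5 other settings (adjusted p from 0.0137 to 0.0381). They also passed without wild-type Foxp3+ replicate 2 (adjusted p = 0.0397), wild-type Foxp3- replicate 1 (adjusted p = 0.044), knockout Foxp3+ replicate 2 (median 1.09, adjusted p = 0.000399) or knockout Foxp3- replicate 2 (adjusted p = 0.0406). Erythroid markers, which had a median of -0.584 and a camera adjusted p = 0.238, passed without knockout Foxp3+ replicate 2 (median -0.965, adjusted p = 0.017). Median and mean differed in sign for conventional CD4 T genes (0.23 and -0.36, test upward), TNF receptor genes (0.07 and -0.13, test downward) and lineage factors (0.10 and -0.06, test upward), none of which passed.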

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

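The tests on a second neutrophil list and on other cell types were chosen before their results were seen, while the tests on mice and sorts, on gene positions, on Foxp3+ or NK cells in the knockout Foxp3- sort and on handling stress were chosen only after the result was seen, and the limits for gene positions, NK cells and handling stress were revised after a look at the values.

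The knockout effect differed between Foxp3+ and Foxp3- thymocytes for 578 genes, by a test of the difference itself (interaction term). The 3 patterns that follow are weighed first, and the other values are given after them.

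Neutrophil genes were high in wild-type Foxp3+ arrays and lower in knockout Foxp3+ arrays, with S100a9 at 11.6 and the granule gene Pglyrp1 at 10.6 in wild type. Pglyrp1 was also at 7.69 on both wild-type and at 8.54 and 8.51 on knockout Foxp3- arrays, so that not all of its signal need be RNA of neutrophils. A second neutrophil list (13 of 23 genes tested, of which Anxa1 is also expressed by T cells) had a median of -1.03 between the genotypes in Foxp3+ cells, with 9 genes lower. Its median between the fractions in wild type was 1.16. Cxcr2, Stfa1, Prtn3 and Ctsg of this list were at background on all arrays but the wild-type Foxp3+ arrays. They passed the detection filter only through these and could come out only lower in knockout, and the median lay close to the limit set beforehand. RNA of neutrophils in the wild-type Foxp3+ samples is thus no more than a candidate explanation, and how far the sort kept out such cells is unknown. A lower share of T cells in that material would raise every other cell type alike. Erythroid genes had a median 1.67 above that of the neutrophil list, more than its median absolute deviation of 0.738. Macrophage genes (median -0.257, 0 of 14 lower) lay 0.772 above it, short of the limit of 1 set beforehand for both lists. Erythroid genes were also higher in knockout Foxp3- arrays (median 0.973, 4 of 6 called), so that their rise was not confined to Foxp3+ cells. The test therefore does not decide on a lower share of T cells. A difference between the mice or sorts of the genotypes cannot be told apart from the genotype, since the labels hold 0 characteristics that name an animal or a sort, and a true difference of genotype stays open and untested.

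Knockout changes of the same direction in both fractions (210 genes, 198 of them placed) were crowded along the chromosomes. Chance positions are argued against by a hypergeometric test per chromosome (smallest adjusted p = 8.26e-06), and 50% of the shared genes had another among their 10 nearest tested genes on each side, against 35.0% after shuffling (permutation p = 0.0003) and a mean of 35.0% for as many genes called in Foxp3- cells only. Chromosome segments of another strain, carried with the floxed alleles, may have caused the crowding on the chromosome of Tcf12, which held 31 shared genes against 11.6 expected, while genes called in Foxp3- cells only were at 104 against 102. Tmem108, Cpne4, Pclaf and Il10ra, named in the comparisons above, lay there in runs of neighbouring shared genes. For these, an effect of such segments cannot be told apart from an effect of E-protein loss. As the direct cause of all shared changes, segments around the floxed alleles are argued against, since 157 of the 198 lay on chromosomes that hold neither Tcf12 nor Tcf3, against at most 9.90 false calls allowed by the adjusted p. The chromosome of Tcf3 held 10 against 9.76 expected. The chromosome of Gdpd3 held 33 against 16.1 (adjusted p = 0.000535), for which no cause was tested. Gdpd3, Nfkbib and Fosb lay there in runs of neighbouring shared genes, and Hbb-b2 lay there outside such runs. Segments in other places, indirect effects of a segment and loss of E proteins in both fractions stay open for the rest.

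Of 25 Treg-signature genes, 11 were higher and 5 lower in knockout than in wild-type Foxp3- arrays (median 0.29), and of 13 T helper effector genes 10 were higher and 0 lower (median 0.67), with an adjusted p of 0.166 for each list with an estimated correlation. Foxp3+ cells left in the knockout Foxp3- sort are argued against, since the rise of Socs2, Itgae, Nrp1, Nt5e and Rgs1 would need a median share of 28.0% Foxp3+ RNA, and the Foxp3 signal changed by -0.00853 of the rise this would bring. NK or NKT cells in that sort cannot be told apart from a rise within the other sorted cells. The list of NK, NKT and cytotoxic markers (11 tested) had a median of 0.491 with a median absolute deviation of 1.33, with 4 genes higher and 1 lower. Whether the sort removed NK cells is unknown, and NKT cells were not tested apart. Ccl5 and Nkg7 of this list rose by 4.65 and 2.41 (to 11.3 and 11.1), and activated T cells also express them. Of the other members, Xcl1 (1.70), Klrd1 (1.52), Klrk1 (0.779) and Cd7 (0.491) also had higher values in knockout Foxp3- arrays. Klrb1c (-0.0967), Klra7 (0.0373), Fcer1g (-0.285) and Tyrobp (-0.403, at background on both knockout Foxp3- arrays) were not called higher, and Plac8 was at -1.20. The members thus went both ways, and the level that an NK share would bring was not measured, so that they do not decide the question. Handling stress of the knockout cells cannot be told apart from genotype, because each sort had its own arrays. The T helper effector list had a median of 0.171 in Foxp3+ cells, where 3 stress genes rose against 7 in Foxp3- cells. RNA of NK or NKT cells, a rise driven by stress in the Foxp3- sort and an effect of E-protein loss therefore all stay open.

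Of the gene lists, 13 differed between the fractions by camera with the preset correlation, and 0 with an estimated correlation. The median differences were -0.32 for the Treg signature, 0.35 for the TCR response, -0.23 for the NF-kB pathway, -0.55 for cytokine receptors and JAK-STAT, -0.66 for chemokine receptors, -0.23 for mature single-positive genes and -0.64 for T helper effector genes. They were 0.71 for the cell cycle and -0.10 for dissociation stress. Among markers they were 0.95 for double-positive thymocytes (0.249 and 1.58 without knockout Foxp3+ replicates 1 and 2), -1.14 for NK and cytotoxic cells, -0.59 for B cells (-0.919 and -0.187 without the same arrays) and -1.26 for myeloid cells. Without knockout Foxp3+ replicate 2 the medians were 0.226 for the TCR response, -0.352 for mature single-positive genes and -0.218 for dissociation stress, which was at -0.0676 without wild-type Foxp3+ replicate 1, and the Treg signature was at -0.491 without wild-type Foxp3- replicate 1.

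Differences of single genes between the knockout effects (Foxp3+ minus Foxp3-) that passed are given here as log2 values. Myeloid-associated genes were at -4.28 (Il1b), -4.24 (Retnlg), -4.03 (Slpi), -3.76 (Hdc), -3.74 (Fcer1g), -3.42 (Lcn2), -3.40 (Lyz2), -3.01 (Chil3), -3.00 (S100a9), -2.93 (S100a8) and -2.27 (Ngp). Chemokines and their receptors were at -5.10 (Ccl5), -3.98 (Cxcr5), -3.03 (Ccr6) and -2.39 (Cxcr3). Genes of cytokine signalling and effector function were at -2.80 (Socs2), -2.58 (Socs3), -1.57 (Cish), -1.25 (Il10ra), -2.05 (Ifng), -1.45 (Fasl), -1.03 (Traf1) and -3.14 (Casp1). Surface and other lymphocyte genes were at -2.55 (Dapl1), -2.41 (Rgs1), -2.35 (Ly6c1), -1.85 (Nrp1), -1.80 (Nt5e), -1.68 (Itgae) and -1.48 (Klrg1), stress genes at -2.98 (Ier3) and -2.33 (Fosb), and the globin Hba-a1 at -2.75. Positive differences were 2.39 (Xist), 1.84 (Akr1c18), 1.75 (Slc15a1), 1.73 (Esco2), 1.66 (Pclaf), 1.22 (Tmem108), 1.10 (Cpne4), 0.98 (Gdpd3) and 0.86 (Tyms, named after its values were seen). Both arrays of at least 1 group were at background for Il1b, Retnlg, Lcn2, Chil3, Ngp, Klrg1, Akr1c18, Slc15a1, Esco2, Pclaf, Tmem108 and Cpne4, so that the size and order of these differences depend on the background correction and are not exact.

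Some of these calls ended when 1 array was left out. For Itgae (adjusted p = 0.0264) they ended without wild-type Foxp3+ replicate 1 (0.0891) or 2 (0.0959), wild-type Foxp3- replicate 1 (0.0946) or 2 (0.0928) and knockout Foxp3- replicate 1 (0.0822) or 2 (0.0883), and with no filter (0.0551). For Tyms (adjusted p = 0.0242) the same arrays gave 0.0864, 0.0593, 0.053, 0.0978, 0.0861 and 0.0786. Tmem108 (adjusted p = 0.0157) reached 0.0725 and 0.056 without wild-type Foxp3- replicates 1 and 2 and 0.0576 without knockout Foxp3- replicate 2. Cpne4 (adjusted p = 0.0114) reached 0.0525 without wild-type Foxp3+ replicate 1, 0.0571 without wild-type Foxp3- replicate 2 and 0.051 without knockout Foxp3- replicate 1. Gdpd3 (adjusted p = 0.00969) reached 0.0503 without wild-type Foxp3- replicate 2, and Klrg1 (adjusted p = 0.0105) reached 0.0537 without wild-type Foxp3- replicate 1.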

How the results depend on the processing

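The alternatives were chosen before the data were examined, except the tests of the direction of the knockout effect in Foxp3- thymocytes, which were chosen only after the result was seen. Of 76 counts and correlations under settings other than leaving out an array, 58 stayed within 1.5 times the reported count, or within 1 SD for the correlation, and 18 moved. None of the 184 gene values or 125 list results reversed direction with a passing test. Among 1963 gene values under these settings, 1938 stayed on their side of the threshold, 10 lost the call and 15 gained it. Among 1350 list results, 1298 stayed, 5 lost the call and 47 gained it. With 1 array left out, 1428 of 1472 gene values and 968 of 1000 list results stayed.

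Without background correction, from the deposited values and with a trended robust variance, the knockout count in Foxp3+ thymocytes (497) was 908, 911 and 892. The count of differing knockout effects (578) was 918, 914 and 911, and that of shared genes (210) 424, 423 and 389, under the same settings. With array weights the Foxp3+ knockout count was 304 and the shared count 133, and with only the 4 arrays compared 140 and 64. The count between fractions in knockout (2589) was 1591 with only the 4 arrays, a fit with fewer samples. The correlation between the knockout effect in Foxp3- cells and the wild-type fraction difference (0.442) was 0.459 without background correction, from the deposited values or with the stricter filter, and 0.462 with cyclic loess. The cause of these changes, those with only 4 arrays included, was not tested.

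Leaving out 1 array at a time, with the normalized values, probes and filter kept and a lone array assumed to vary like the other groups, gave 160 to 817 genes for the knockout in Foxp3+ and 829 to 2652 in Foxp3- cells. It gave 2003 to 3844 between fractions in wild type, 1348 to 2468 in knockout, 224 to 790 for the difference, 64 to 369 for the shared genes and 0.421 to 0.461 for the correlation. The labels number replicates alike in all groups without saying whether numbers pair arrays. With the replicate block, the counts were 385, 1935, 3212, 2425 and 478, and 158 shared genes. The deviations of same-numbered arrays correlated across genes at -0.03 to 0.11 between groups. Signal over background limits genes near the floor, where folds are given as lower bounds.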

Other observations

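The list of macrophage genes and its comparison between the genotypes in Foxp3+ cells were chosen before their result was seen, while the other tests of this part were chosen only after the result was seen.

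A list of macrophage genes was set beside the markers described so far. Of its 14 tested genes, 12 were higher in wild-type Foxp3+ than in Foxp3- thymocytes, with a median of 1.40. In knockout against wild-type cells its median was -0.257 in Foxp3+ and 0.057 in Foxp3- thymocytes, with 0 genes called lower in the former. Adgre1, a macrophage surface receptor, was at 7.47 and 7.40 on the wild-type and 6.86 and 7.17 on the knockout Foxp3+ arrays, against 4.24 to 4.46 on the Foxp3- arrays. Axl, a receptor for dying cells, was at 9.93 and 9.94 on the wild-type and 10.4 and 10.2 on the knockout Foxp3+ arrays.

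Sex-linked genes were looked at because Xist was among the named genes. Xist had log2 values of 6.90 and 7.39 on wild-type and 5.45 and 5.54 on knockout Foxp3- arrays, and of 6.08 and 5.84 on wild-type and 6.73 and 6.67 on knockout Foxp3+ arrays. Among the Y-linked genes, Kdm5d was at 7.17 and 6.74 on knockout Foxp3+ and at 7.61 and 7.87 on knockout Foxp3- arrays (difference -0.786, adjusted p = 0.0136). Eif2s3y was higher in knockout than in wild-type Foxp3- arrays by 0.568 (adjusted p = 0.0458), at 9.99 and 9.96 against 9.38 and 9.44. Uty was at 5.15 to 5.76 on the 8 arrays and was not called in any of the 5 comparisons. The labels give no sex, and no explanation was tested.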
